A study of Mus musculus with 2 samples.

How the data were processed

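DNase-seq peaks and hotspots of 2 biological replicates of whole B6NCrl mouse embryos of embryonic day 10.5, both sexes pooled, were analysed as 1 group. Reads were aligned and peaks and hotspots were called by the authors on each replicate separately, on mm10, per the labels and the text files deposited beside the data. The aligner, the peak caller, their versions and the calling thresholds are not given in the sources used here, nor is any correction for the sequence preference of DNase I. Each deposited peak is 150 bp wide on a 20 bp grid and carries a whole-number score from 2 to 150, whose definition is not stated in the files. On nuclear chromosomes it never reached 150, while on mitochondrial DNA it did, so it is bounded and compresses ratios among strong peaks. It was used to rank and filter peaks within a replicate, and ratios between replicates are given only relative to the median of all peaks or genes, except where stated. The other value columns of the peak files held -1 throughout. Each deposited hotspot carries the −log10 of a q-value, from 1.30, a q of 0.05, up to 6, with 100 for smaller q-values, and this value was not used to filter. The replicates are biological per the labels, and no p-value here measures the spread between them. The depth of the libraries is unknown from the files, so no interval that needs it is given.

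The peak files held 208148 and 229803 lines, of which 28 and 47 repeated another peak and were dropped. Peaks on mitochondrial DNA and on scaffolds were left out of the comparisons. For shares of overlap and for unshared peaks, peaks of the replicates counted as shared when they overlapped by 1 bp or more. Elsewhere shared peaks were paired one to one, each the other's best overlap. This holds for strength, the strongest shared peaks, distal shared peaks, motifs and chromosomes. Chance overlap and chance location came from 100 circular shifts of replicate 2 peaks over the full length of each chromosome, assembly gaps included. Genes were the 21938 protein-coding genes of GENCODE M21 on GRCm38.p6, whose chromosomes are those of mm10. A gene was open when a peak lay within 1 kb of any annotated TSS in both replicates. Genes named as closed had no such peak in either replicate, which does not show that the promoter was closed in every cell type. Peaks over 1 kb from any TSS were distal and were counted within 50 kb of a gene's TSSs. Peak location was assigned in the order TSS, exon, intron, intergenic.

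The 21 gene lists, 20 motifs, 18 list and motif pairs, the tests, the thresholds and the rule for named genes were fixed before the data were examined. That rule took, in each list, the 3 open genes of highest mean strength and the first 3 closed genes in alphabetical order. Genome-wide it took the 10 strongest shared peaks, the 10 genes with most distal shared peaks, the 5 strongest unshared peaks of each replicate and every Hox gene without a shared TSS peak. Some genes that the rule takes are not reported here. Genes named outside it, and the hotspot width of 2 kb, the gene families, the split of Hox genes by position, the mapped regions and the example sequences, were chosen after seeing the data. The list of late or adult genes was fixed with 31 symbols and 30 matched, since Amy2b is not protein-coding in M21. Receptor genes were taken by symbol prefix, and no symbol in M21 matched the Or form of olfactory receptor names. Some genes stand in several lists, most often in the liver and gut endoderm list, which shares 10 of 24 with others, and in the kidney list, which shares 7 of 18. The markers of decidua, trophoblast, yolk sac and blood were included as other tissues that the sample could hold.

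Gene lists were tested at TSSs with two-sided Fisher's exact tests against all other protein-coding genes, with 95% Wilson intervals that treat genes as independent. Distal counts were set against 10000 random lists matched on the number of neighbouring genes, with a two-sided permutation p whose smallest value is 0.0002. Motifs were searched on both strands, in distal shared peaks and in 150 bp windows 1 kb to each side that overlap no peak, and tested with two-sided Fisher's exact tests. The CATCTG E-box occurs inside some matches of the CTCF core, so their counts are not independent. Promoter CpG content was the observed to expected ratio within 500 bp of the 5'-most TSS of each gene. P-values were adjusted by the Benjamini-Hochberg method within each family of tests, and calls were made at an adjusted p under 0.05. Alternatives changed the overlap, the TSS window, the number of TSSs per gene, the distance for distal peaks, the share of peaks kept, the background and the replicates used. The 5'-most TSS for distal counts was added after seeing the data, as was leaving out each replicate for motifs near lists, chromosomes and hotspots.

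Peak overlap, peak strength, the list test at TSSs, the distal count test and the motif test were run on simulated data. Peak location, chromosomes, hotspots, pairs of a list and a motif, and CpG matching were not simulated. With chance overlap removed, an overlap of 70.0% was returned for a simulated 70.0%. The overlaps of the real data are given without that removal. A median log2 ratio of 0.25 was returned for 0.25, with an SD of 0.32 for 0.30. Of simulated lists with no effect, 4% at TSSs and 2.5% at distal peaks had a p under 0.05, and 0 of 1000 were called at TSSs after adjustment. All lists with 20 of 20 or 7 of 20 open genes were called, and 67% of lists with a doubled mean distal count. A CTCF core planted in 5% of peaks was found in 4.80%, all 3 planted motifs were called in the right direction and 1 other motif, the CATCTG E-box, was called. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.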

Results

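Open chromatin was mapped by DNase-seq in whole mouse embryos of the B6NCrl strain at embryonic day 10.5. In this assay nuclei are treated with the enzyme DNase I, which cuts DNA most readily where nucleosomes have been displaced, and the cut ends are sequenced. At this stage the neural tube, somites, beating heart, limb buds and circulating primitive red cells are all present, so a whole embryo mixes many cell types. Embryos of both sexes were pooled, and 2 biological replicates made up the single group, so no contrast between conditions could be drawn. The questions asked of the data were how far the 2 replicates matched, which genes had open promoters, where the distal open sites lay and which sequence motifs they held. Replicate 1 held 207946 peaks and replicate 2 held 229568 peaks of 150 bp on the nuclear chromosomes, which covered 30.7 and 33.8 Mb. Each peak carried a score deposited by the authors, called peak strength here, with a median of 41 in replicate 1 and 50 in replicate 2. The numbers of sequenced reads were not used here, so the depth behind each peak is unknown. All coordinates are on the mm10 build.

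The strongest open sites shared by both replicates lay at promoters. The highest mean strength was 149 ± 0.707 (SD, n = 2) at the promoter of Hjurp, the chaperone that loads the centromeric histone CENP-A (chromosome 1, 88277536 to 88277685, 22 bp from the transcription start site, or TSS). Next came Ift27, a subunit of the transport machinery of cilia (chromosome 15, 78174196 to 78174345), with strengths of 144 and 147. A shared peak inside Trpm5 and 18 bp from the TSS of Tssc4 (chromosome 7, 143069156 to 143069305) scored 144 and 145. Uvrag, Calr, Hspa2, Ptma, Hsd17b12, Selenof and Tcp1 filled the other places among the 10 strongest shared peaks, and all 10 lay within 1 kb of a TSS.

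Of the peaks of replicate 1, 74.5% overlapped a peak of replicate 2, and 67.6% of the peaks of replicate 2 overlapped one of replicate 1, a mean of 71.0% ± 4.87 (SD, n = 2). When the peaks of one replicate were shifted along each chromosome 100 times, the overlap averaged 2.61% and 2.39%, so the observed overlap was 28.5-fold and 28.3-fold higher (permutation p = 0.0099, the smallest that 100 shifts can give). Overlap rose with strength. In the weakest of 5 equal strength classes 37.1% of replicate 1 peaks were shared, against 97.9% in the strongest, and in replicate 2 the shares were 28.7% and 97.0%. The 53127 unshared peaks of replicate 1 had a median strength of 28 and the 74461 unshared peaks of replicate 2 a median of 36. The strongest unshared peaks still lay at promoters, at Tomm40 (140), Kat6b (139), Gsk3b (138 and 136) and Hdgfl2 (137) in replicate 1, and at Rab8a (138), Zfp78 (136), Hjurp (135), Nlgn2 (135) and Siva1 (134) in replicate 2. Each of these 10 lay inside a hotspot of the other replicate, with a gap of 10 to 190 bp to its nearest peak.

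Strength at shared sites ran in parallel in the replicates. Across 152091 peaks paired one to one, Spearman's rho was 0.901 and Pearson's r of log2 strength was 0.901. Peaks within 1 kb of a TSS had a rho of 0.946 over 40708 pairs and distal peaks a rho of 0.881 over 111383 pairs. The median log2 ratio of replicate 2 to replicate 1 was 0.26 with an SD of 0.29, and the medians were 49 and 61. These correlations are across peaks, which are not independent replicates, so they carry no p-value.

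Promoters of the neural progenitor, early neuron and neural crest lists were all open. All 30 neural progenitor and patterning genes, all 20 early neuron genes and all 20 neural crest genes had a peak within 1 kb of a TSS in both replicates, against 69.7% of the 21938 protein-coding genes. Among neural progenitor genes the strongest promoters were those of the transcription factors Sox11 (132 ± 3.54, SD, n = 2) and Sox9 (131 ± 0.707, SD, n = 2) and of Nes, the intermediate filament nestin (127 ± 3.54, SD, n = 2). In the early neuron list they were Ebf2 (129 and 133 in replicates 1 and 2), Isl1 (122 and 132) and Isl2 (122 and 125), a transcription factor of the Ebf family and a pair of LIM homeodomain factors of motor neurons. In the neural crest list they were Mitf (121 and 129), the regulator of melanocyte fate, Msx1 (124 and 126) and Ets1 (124 in both). Adjusted p-values from Fisher's exact test were 0.000297 for neural progenitors and 0.00308 for each of the other lists, and the 95% Wilson interval for 20 of 20 genes was 83.9% to 100%.

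**Figure D1:**
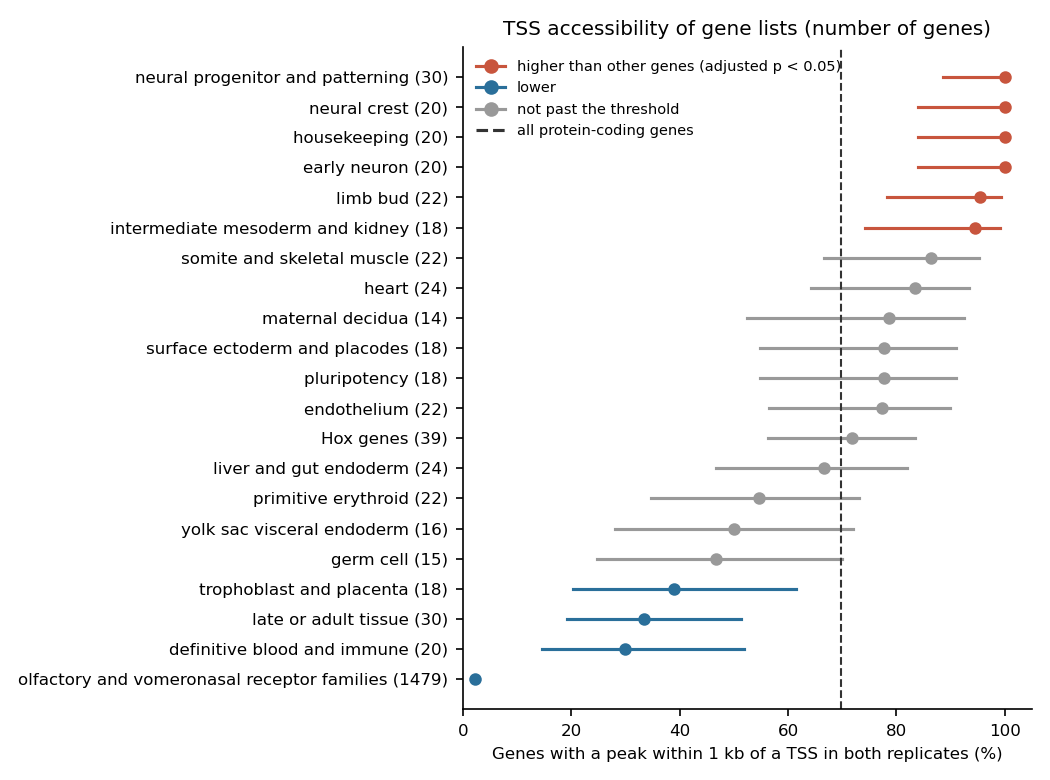
Percent of the genes of each list (vertical axis) with a peak within 1 kb of a TSS in both replicates (horizontal axis), with 95% Wilson intervals as bars and the share of all protein-coding genes, 69.7%, as a reference line. The neural progenitor, early neuron, neural crest and housekeeping lists sit at 100% and the olfactory and vomeronasal receptors at 2.16%.

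Limb bud genes were open in 21 of 22 cases (adjusted p = 0.0132, Fisher's exact test) and genes of the intermediate mesoderm and kidney in 17 of 18 (adjusted p = 0.0418). Sall4 (131 in both replicates), Meis1 (120 and 127) and Irx5 (118 and 127) led the limb list. Fgf8, the growth factor of the apical ridge, had a promoter peak only in replicate 2 (72). Six2, which maintains nephron progenitors, led the kidney list (129 and 120), followed by Emx2 (116 and 120) and Wnt11 (119 and 117). Hoxd11 had a promoter peak only in replicate 1 (65). All 20 housekeeping genes were open (adjusted exact p = 0.00308), with the ribosomal protein gene Rpl13a (139 and 144), the elongation factor gene Eef1a1 (132 and 138) and Polr2a, the large subunit of RNA polymerase II (131 and 137), at the top. The kidney list was no longer called at TSS windows of 500 bp (adjusted exact p = 0.131) or 2500 bp (0.110), with 1 TSS per gene (0.224) or with replicate 2 alone (0.0718).

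Olfactory and vomeronasal receptor genes, which are used in sensory neurons of the nose, were nearly all closed. Only 32 of 1479 (2.16%) had a promoter peak in both replicates, and the exact p lay below the smallest number that double precision can hold. Olfr1, Olfr10 and Olfr1000 had none, while Vmn1r4 (116 and 130), Olfr156 (74 and 98) and Olfr94 (78 and 79) were the strongest exceptions. Whether reads could be placed uniquely in these large gene families was not examined. Genes of late or adult tissues were open in 10 of 30 cases (adjusted p = 0.000432, Fisher's exact test). Those without a peak included the pancreatic carboxypeptidase gene Cpa1 and the casein genes Csn1s1 and Csn2, and those with one were led by Krt10 (112 and 123), Gnat1 (94 and 110) and Gfap (90 and 107). Definitive blood and immune genes were open in 6 of 20 cases (adjusted exact p = 0.00151). Cd4 and Cd79a, surface molecules of lymphocytes, were among the closed genes, and the transcription factor genes Pax5 (125 and 128), Gata2 (115 and 117) and Runx1 (110 and 116) were open. Trophoblast and placenta genes were open in 7 of 18 cases (adjusted exact p = 0.0187), with Ctsq, Gcm1 and Prl2c2 closed and Ascl2 (95 and 99), Tfap2c (85 and 108) and Peg10 (93 and 95) open. With 1 TSS per gene the open share fell to 20% of late or adult, 15% of immune and 27.8% of trophoblast genes, all still lower. Against genes of like promoter CpG content, given below, the late or adult, immune and trophoblast calls were lost.

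The remaining lists did not pass the test. Heart genes were open in 20 of 24 cases (adjusted p = 0.258, Fisher's exact test), led by Tbx3 (129 and 130), Isl1 (122 and 132) and the sarcomere gene Actn2 (119 and 126), with Tnnc1 closed. Somite and skeletal muscle genes were open in 19 of 22 cases (adjusted exact p = 0.171), led by Pax9 (126 and 127), Tbx18 (122 and 131) and Foxc1 (121 and 124). Msgn1, a gene of the presomitic mesoderm, and Myf6, a late muscle factor, were closed. Among primitive erythroid genes 12 of 22 were open (adjusted exact p = 0.241). Zfpm1, the cofactor of GATA1, was the strongest (124 and 135), ahead of Epor (85 and 102) and Lmo2 (82 and 102), while Alas2, Cldn13 and Gata1 were closed. Alas2 and Gata1 lie on the X chromosome, where 52.5% of genes were open against 71.1% on autosomes. The embryonic and adult globin genes Hba-x, Hba-a1, Hbb-bh1 and Hbb-y, named after their values were seen, had no promoter peak in either replicate. In a mixture of many cell types a promoter open in a small share of cells may have no called peak. A missing peak therefore does not show that these promoters were closed in the cells that use them. Endothelial genes were open in 17 of 22 cases (adjusted exact p = 0.710), with Notch4 (116 and 124), Fli1 (98 and 109) and Kdr (97 and 109) strongest and Eng, Nos3 and Tek closed. Liver and gut endoderm genes were open in 16 of 24 cases (adjusted exact p = 0.863), with Foxa3 (130 and 139) and Prox1 (112 and 116) among the strongest. Alb, Apoa1 and Hnf4a, genes of differentiated hepatocytes and visceral endoderm, were closed.

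Surface ectoderm and placode genes were open in 14 of 18 cases (adjusted p = 0.710, Fisher's exact test), with Pitx3 the strongest (121 and 128) and Krt14 closed. Pluripotency genes were also open in 14 of 18 cases (adjusted exact p = 0.710). The open ones were led by Tbx3, Klf5 (121 and 122) and Klf4 (101 and 123), and Dppa4, Dppa5a and Zfp42 were closed. Germ cell genes were open in 7 of 15 cases (adjusted exact p = 0.164), with Tex14 (114 and 130), Kit (115 and 122) and Dazl (114 and 118) open and Ddx4, Hormad1 and Mael closed. At 33.3% open, the germ cell list was called lower with a TSS window of 500 bp (adjusted exact p = 0.0215), with 1 TSS per gene (0.0252) and with the stronger 50% of peaks (0.0239). Yolk sac visceral endoderm genes were open in 8 of 16 cases (adjusted exact p = 0.171), with Dab2 (113 and 112), Lrp2 (91 and 101) and Apob (80 and 94) open and Apoa1, Apoa4 and Apom closed, and with 1 TSS per gene the share was 25% and the list was lower (adjusted exact p = 0.00413). Of the markers of maternal decidua 11 of 14 were open (adjusted exact p = 0.710). Hoxa10, Foxo1 and Hand2, which embryonic tissues also use, were open, and the decidual prolactins Prl6a1 and Prl8a2 were closed.

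Of the 39 Hox genes, the transcription factors that pattern the body axis, 28 were open (71.8%, adjusted p = 0.863, Fisher's exact test). Hoxc13 (112 and 123) and Hoxa7 (108 and 121) were among those with the strongest promoters. All 10 Hoxb genes were open, with 9 of 11 Hoxa, 5 of 9 Hoxc and 4 of 9 Hoxd genes. Hoxa6, Hoxc9, Hoxc11, Hoxc12, Hoxd12 and Hoxd13 had no promoter peak in either replicate. Hoxd8 (83), Hoxd9 (72), Hoxc8 (71), Hoxd11 (65) and Hoxa11 (61) had one in replicate 1 only.

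Several list calls changed against genes with a like promoter CpG content. Against 10000 random lists matched on this content at the 5'-most TSS, early neuron genes (100% against a random median of 75%, adjusted permutation p = 0.00315) and heart genes (83.3% against 62.5%, 0.0210) were higher. A peak at any TSS made a gene open, and the number of TSSs was not matched, so an effect of that number is not excluded. Hox genes were lower (71.8% against 92.3%, adjusted permutation p = 0.0014), as were germ cell genes (46.7% against 86.7%, 0.0014) and the receptors (2.16% against 22.3%, 0.0014). The Hox call depends on replicate 2. With replicate 1 alone, an alternative chosen after seeing the data, 84.6% of Hox genes were open, inside the 82.1% to 97.4% of matched lists (adjusted permutation p = 0.375). The calls of the trophoblast (38.9% against 50%, adjusted permutation p = 0.560), immune (30% against 45%, 0.470) and late or adult (33.3% against 36.7%, 1) lists ended. For the housekeeping (adjusted permutation p = 0.337), neural progenitor (1), neural crest (0.239), limb bud (1) and kidney (1) lists the 95% range of matched lists reached 100%. No share of open genes could therefore be called higher in these 5 lists, and the matched test does not decide their calls. Their observed shares were 100%, 100%, 100%, 95.5% and 94.4% in that order. The matched medians were 90%, 96.7%, 90%, 90.9% and 88.9%, against 69.7% of all protein-coding genes. All list p-values set genes against other genes in these 2 libraries and do not measure the spread between embryos.

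Distal peaks were crowded around genes of patterning and organ formation. Several peaks of 150 bp can lie side by side in 1 wide hotspot, so these counts are not numbers of separate sites. The list test was not run without peaks in wide hotspots. Of the 111383 shared peaks over 1 kb from any TSS, Hox genes had a median of 16 within 50 kb of their TSSs, neural progenitor genes 13.5, limb bud genes 12.5 and surface ectoderm and placode genes 12.5, against 5 for all protein-coding genes. Neural crest genes had a median of 11.5 and kidney genes 10.5. Against 10000 random lists of genes with as many neighbours, the first 4 lists and the receptors (median 0, lower) had an adjusted permutation p of 0.00084, from a p of 0.0002, the smallest these lists can give. The permutation p treats genes as independent. Clustered Hox genes are not, since only 131 distinct distal shared peaks lay within 50 kb of the 39 genes and neighbours counted the same ones.

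Neural crest (adjusted permutation p = 0.0021), kidney (0.0105), heart (median 9.5, 0.0105), liver and gut endoderm (9, 0.0294), endothelium (8.5, 0.0294), early neuron (9, 0.0472) and decidua genes (9.5, 0.0472) were also higher. Somite (median 8, adjusted permutation p = 0.148), housekeeping (7, 0.281), yolk sac (6.5, 0.608) and erythroid genes (5.5, 0.817) were not called. Pluripotency, trophoblast, immune and late or adult genes had a median of 6 (adjusted permutation p = 0.744 for each), as did germ cell genes (0.865). The 10 genes with the most distal shared peaks were Foxp1 with 74, Nav2 with 66, Bcas3 with 60, Auts2, Frmd4a, Gse1 and Kalrn with 57 each, Adamts18 with 52, and Pde4d and Rere with 51 each. Many of these have TSSs spread over long stretches, 593 kb in Foxp1 (chromosome 6, 98925338 to 99522721) and 1485 kb in Pde4d. With the 5'-most TSS alone, an alternative chosen after seeing the data, the highest counts were 39 at Abt1 and Btn1a1 and 37 at Kdm6b.

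**Figure D2:**
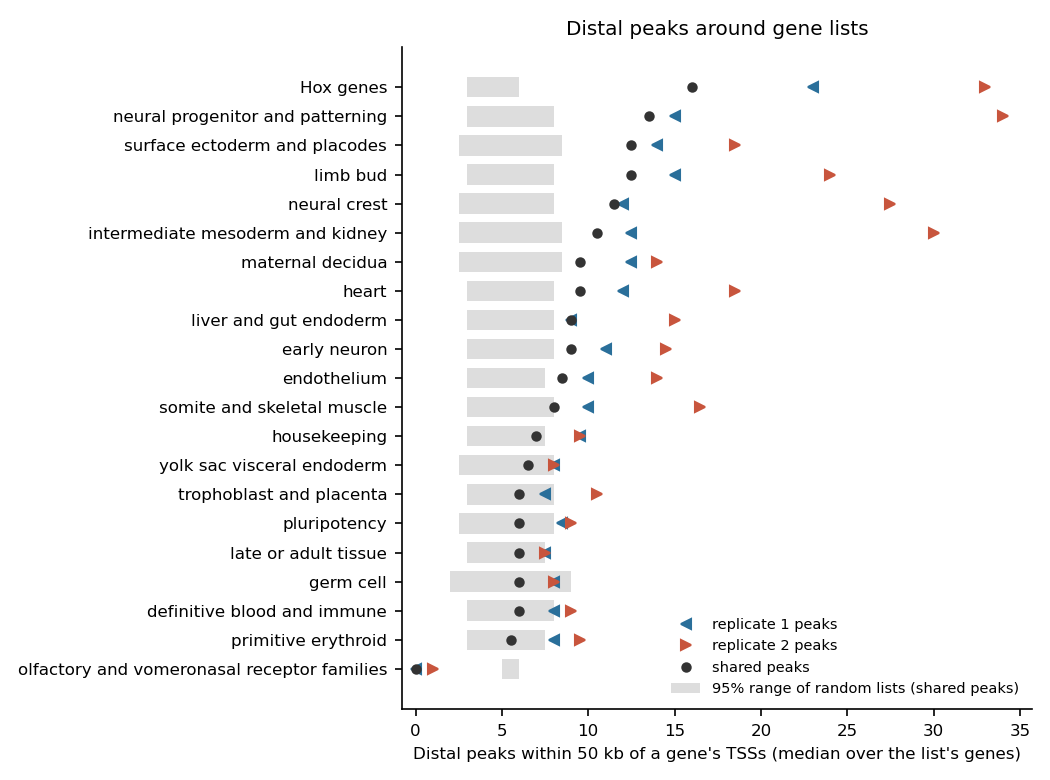
Median number of distal shared peaks within 50 kb of the TSSs of the genes of each list (horizontal axis, number of peaks), as dots for shared peaks and triangles for the peaks of each replicate, with the 95% range of 10000 matched random lists for shared peaks as a grey bar. Hox genes at 16 and neural progenitor genes at 13.5 lie above their random ranges, which end at 6 and 8.

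The distal counts differed between replicates around the same genes. Neural progenitor genes had a median of 15 distal peaks in replicate 1 and 34 in replicate 2, kidney genes 12.5 and 30, neural crest genes 12 and 27.5, limb bud genes 15 and 24, and Hox genes 23 and 33. Housekeeping genes had 9.5 in both replicates and late or adult genes 7.5 in both. With replicate 1 alone, 5 of the 11 lists called higher were still called (neural progenitor, heart, limb bud, surface ectoderm and Hox). The others were not (neural crest and decidua, adjusted permutation p = 0.0723, kidney 0.0552, early neuron and endothelium 0.124, liver and gut endoderm 0.522), and with replicate 2 alone 12 lists were higher, somite genes among them (0.000525). Over 7 alternatives the calls of the neural progenitor, limb bud and surface ectoderm lists were never lost. The decidua call was lost in 6, liver and gut endoderm in 5, endothelium in 4, early neuron in 3, heart and neural crest in 2 each, and Hox and kidney in 1 each. The number of lists called higher was 6 at 100 kb, 9 at 20 kb, 7 with the stronger 50% of peaks and 6 with each peak counted for its nearest TSS only. In that last setting the clustered Hox genes had a median of 1 (adjusted permutation p = 0.399).

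Long stretches of open chromatin marked developmental regulators in replicate 2. Its widest hotspot, a region of raised DNase I cutting called by the authors, spanned 15201 bp at Dmrta2 (chromosome 4, 109973215 to 109988415). The next spanned 15132 bp at the forkhead gene Foxf2 (chromosome 13, 31617857 to 31632988), where hotspots of replicate 1 covered 1353 bp. Emx2 (14585 bp), Ebf3 (14457 bp), Sim1 (14062 bp), Foxa2 (13808 bp), Bahcc1 (12882 bp), Sox2 (12151 bp) and the neighbours Zic1 and Zic4 (12020 bp) were also among the 10 widest. The widest of replicate 1 was 6721 bp at Tnrc18, ahead of Tgif1 (5470 bp), Zfp36l1 (5457 bp), Myc (4905 bp) and Hoxa2 (4861 bp).

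Hotspots over 2 kb, a width chosen after seeing the data, numbered 635 in replicate 1 and 4424 in replicate 2. In replicate 2 they held a TSS of 14 of 18 kidney genes (adjusted p = 2.24e-07, Fisher's exact test), 16 of 22 limb bud genes (2.24e-07), 19 of 30 neural progenitor genes (2.24e-07) and 11 of 20 neural crest genes (0.00076), against about 17.6% of other genes. Early neuron (10 of 20, adjusted p = 0.00338), heart and endoderm (11 of 24 each, 0.00353), somite (9 of 22, 0.0191), housekeeping (8 of 20, 0.0304) and surface ectoderm genes (7 of 18, 0.0488) were also higher by Fisher's exact test. Late or adult genes (0 of 30, adjusted exact p = 0.0147) and receptors (0 of 1479, 3.93e-129) were lower. These lists had few open promoters (10 of 30 and 32 of 1479), and every hotspot overlapped a peak. Their lower calls, here and with replicate 1 below, therefore add little to that. For the higher calls too, other genes were not matched on open promoters or CpG content. With the 635 wide hotspots of replicate 1 no list was called higher. Limb bud genes came closest, with 3 of 22 against 2.83% of other genes (adjusted exact p = 0.247). Only the receptors were lower (0 of 1479, adjusted exact p = 2.65e-18). With the 4424 widest hotspots of replicate 1, a number chosen after seeing the data, housekeeping genes were higher (9 of 20, adjusted exact p = 0.0436). Late or adult genes (0 of 30, adjusted exact p = 0.0437) and receptors (1 of 1479, 6.53e-126) were lower, and no other list was called.

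Over the whole genome the replicates held similar numbers of hotspots, 188404 and 188191, but these covered 60.0 Mb in replicate 1 and 79.0 Mb in replicate 2. Median widths were 245 and 260 bp. Of the hotspots of replicate 1, 78.9% overlapped one of replicate 2, and 69.9% in the other direction, a mean of 74.4% ± 6.32 (SD, n = 2). Every nuclear peak overlapped a hotspot of its replicate and every hotspot overlapped a peak. In the 80 kb around Foxf2 (chromosome 13, 31585816 to 31665815), hotspots covered 1.99 kb with 8 peaks in replicate 1 and 21.3 kb with 41 peaks in replicate 2. Across the HoxD cluster (chromosome 2, 74653310 to 74777979) they covered 22.1 kb with 71 peaks in replicate 1 and 30.4 kb with 75 peaks in replicate 2.

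**Figure D3:**
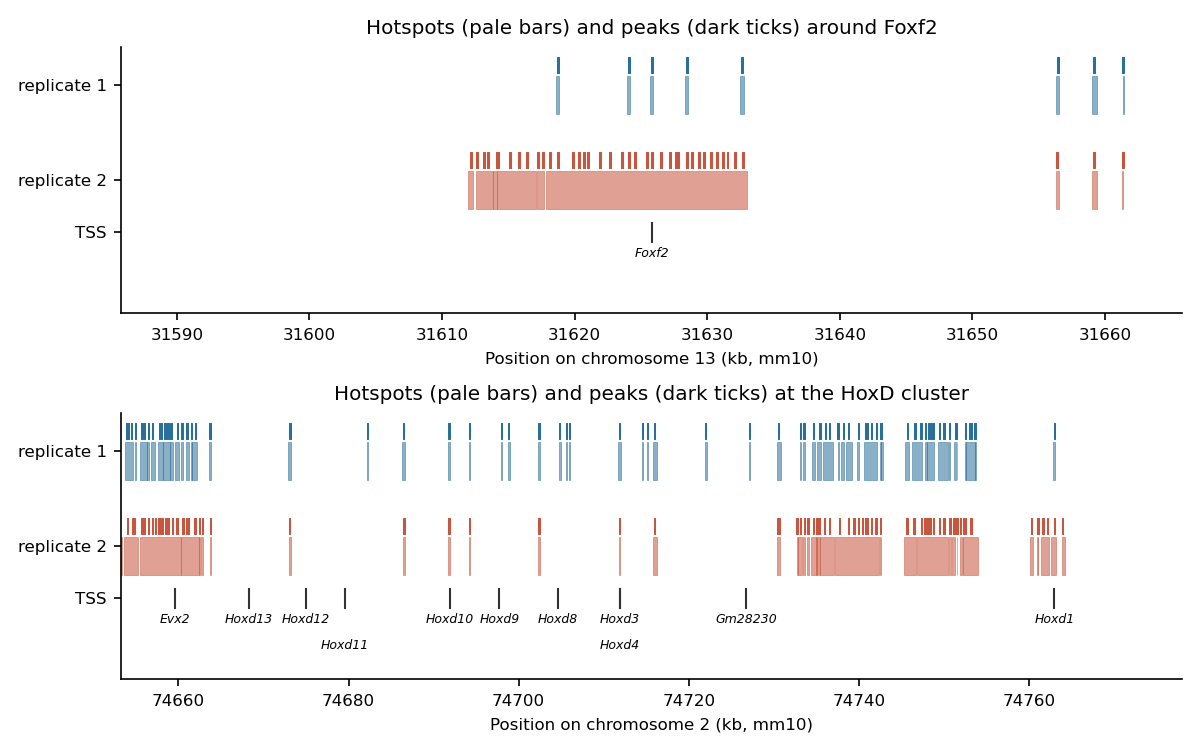
Maps of the Foxf2 region on chromosome 13 and the HoxD cluster on chromosome 2 (horizontal axis, position on mm10), with peaks as dark ticks and hotspots as pale bars for each replicate, marks at the TSSs of protein-coding genes, and narrow features drawn at a minimum visible width. Around Foxf2 hotspots cover 2.49% of the region in replicate 1 and 26.6% in replicate 2, and across HoxD 17.8% and 24.4%.

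The motif of CTCF, the factor that anchors chromatin loops, had the highest odds ratio of the motifs found in both distal peaks and windows. Its core (CCASYAGRKGGC, in the letter code for mixed bases) was present in 5.44% of the 111383 distal shared peaks and in 0.0281% of 199401 flanking windows, an odds ratio of 203 (95% interval 156 to 264). Over the alternatives this ratio ran from 129 without replicate 1 to 323 for the stronger 50% of peaks, and was 140 without replicate 2. The share rose with peak strength, from 1.58% in the weakest of 5 classes to 13.9% in the strongest. The motif of REST, the repressor of neuronal genes outside neurons, was found in 95 peaks and in 0 windows. E-box CAGCTG, which myogenic and other bHLH factors bind, was present in 17.2% of peaks against 6.34% of windows (odds ratio 3.08), and E-box CATCTG in 19.8% against 11.3% (1.95).

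Odds ratios were also raised for the nuclear receptor pair (7.72), NRF1 (5.08), SP/KLF (3.18), MEIS (3.14), ETS (2.31), TFAP2 (2.15), TEAD (1.99), AP-1 (1.46), SOX (1.29), OCT (1.13) and NFY (1.08). GATA (18.2% of peaks against 25.5% of windows, odds ratio 0.651), homeobox (0.885) and FOX motifs (0.742) were lower. MEF2 (odds ratio 1.07, adjusted p = 0.357, Fisher's exact test) and HNF1 (0.964, adjusted p = 1) did not differ from the windows by this test. Peaks had a mean GC content of 49.9% and windows 44.0%. In windows matched on GC content, homeobox (odds ratio 2.02) and FOX motifs (1.24) turned higher, MEF2 was called higher (1.98), GATA was still lower (0.922) and NFY was no longer called (1.04, adjusted p = 0.0536, Fisher's exact test). The odds ratios of NRF1 (2.82), SP/KLF (1.69) and TFAP2 (1.32) were then lower, though still called, and those of OCT (1.90) and HNF1 (2.33, not called) were higher. CTCF remained the highest odds ratio of motifs found in both sets, at 138. Against windows with under 10% soft-masked repeat the homeobox motif was also higher (1.13), OCT lost its call with replicate 1 alone (1.06, adjusted exact p = 0.0878), and NFY lost it with flanks 5 kb away (1.01, 0.528). MEF2 was also called higher with replicate 1 alone (1.19, adjusted exact p = 0.00332) and with flanks 5 kb away (1.20, 0.00986).

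**Figure D4:**
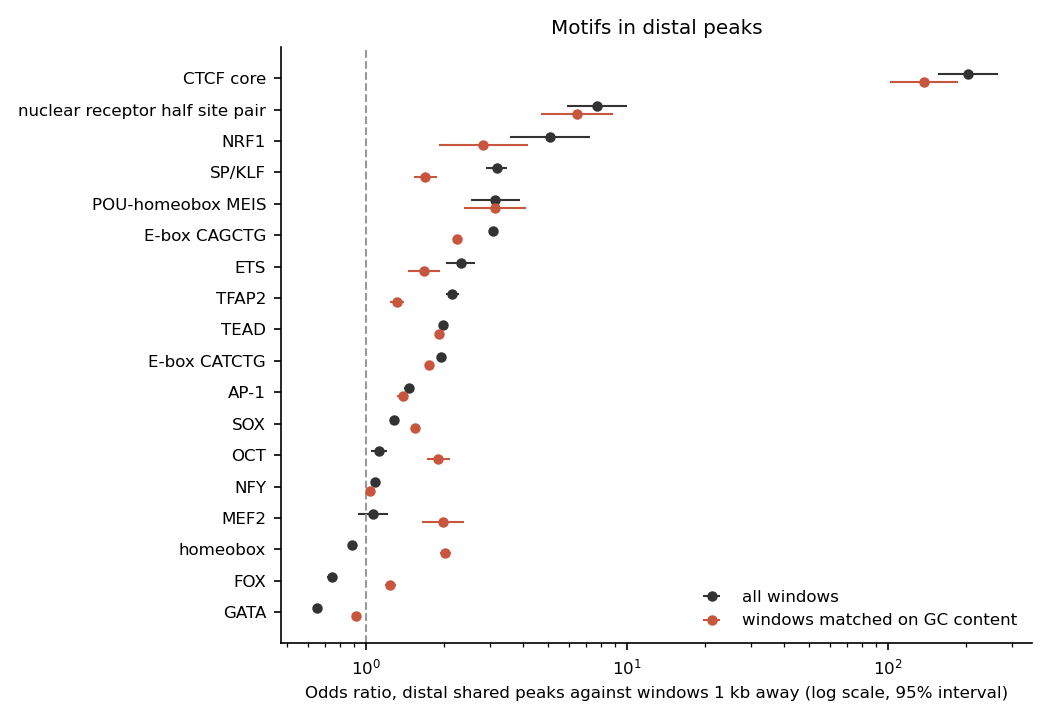
Odds ratio of each motif in distal shared peaks against flanking windows (horizontal axis, logarithmic), for all windows and for windows matched on GC content, with 95% intervals as bars. CTCF lies farthest to the right at 203 and 138, the homeobox motif moves from 0.885 to 2.02, and REST, with 0 windows, and HNF1, with 10 peaks, are not drawn.

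The strongest distal shared peak with a CTCF core, picked after seeing the data, lay inside Sept9, 1345 bp from its TSS (chromosome 11, 117267516 to 117267665), with strengths of 132 and 130. Its sequence is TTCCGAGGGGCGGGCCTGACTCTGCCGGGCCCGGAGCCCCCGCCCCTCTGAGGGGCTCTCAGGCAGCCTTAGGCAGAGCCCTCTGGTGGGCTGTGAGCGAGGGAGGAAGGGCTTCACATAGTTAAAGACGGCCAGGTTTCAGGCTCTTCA, and the motif matches the minus strand at GCCCTCTGGTGG (117267593 to 117267604). The strongest with a REST motif lay in no protein-coding gene, 6047 bp from the TSS of the potassium channel gene Kcnh2 (chromosome 5, 24357576 to 24357725), with strengths of 108 and 110. Its sequence is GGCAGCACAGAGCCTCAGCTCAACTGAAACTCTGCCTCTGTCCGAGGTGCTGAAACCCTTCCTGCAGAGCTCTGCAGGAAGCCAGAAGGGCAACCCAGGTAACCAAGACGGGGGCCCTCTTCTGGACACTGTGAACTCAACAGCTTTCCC, with the match on the minus strand at CTGTCCGAGGTGCTGAA (24357613 to 24357629).

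None of 18 pairs of a list and a motif passed the test as higher in distal peaks near the genes of the list, and 2 were lower. E-box CATCTG was found in 42 of 407 distal peaks near neural progenitor genes, 10.3% against 19.9% elsewhere (adjusted p = 4.96e-06, Fisher's exact test), and the CTCF core in 0 of 131 distal peaks near Hox genes, against 5.45% elsewhere (adjusted p = 0.0130). Peaks within 1 kb of a TSS are left out here, so the Hox result does not show that the clusters lack CTCF sites. Peak strength, with which the CTCF share rose, was not matched, and peaks of the same cluster are not independent. GATA motifs lay in 20.5% of the distal peaks near erythroid genes and 21.4% of those near heart genes, against 18.2% elsewhere (adjusted exact p = 0.893 and 0.720). TFAP2 motifs lay in 4.24% of those near neural crest genes, against 2.21% elsewhere (p = 0.0440, adjusted p = 0.264, Fisher's exact test). With GC-matched peaks, the unadjusted permutation p was 0.115 for this pair, 0.0478 for GATA near heart genes and 0.0414 for homeobox near limb bud genes, and none of these was called.

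In relative strength of replicate 2 to replicate 1, most gene lists stayed within the range of random lists of equal strength. At promoters neural progenitor genes lay 0.13 above the median of all genes on the log2 scale (95% range of random lists -0.02 to 0.09). At distal peaks Hox genes lay 0.20 above it (-0.06 to 0.02), limb bud genes 0.09 (-0.05 to 0.06), housekeeping genes 0.09 (-0.05 to 0.07), neural progenitor genes 0.08 (-0.05 to 0.05) and receptors 0.07 (0.02 to 0.05). Somite genes lay at -0.05, just below their range. These 6 of 21 lists fell outside the range in at least 1 measure, as a description of 2 libraries with no p-value.

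Peaks were concentrated at promoters and depleted between genes. Within 1 kb of a TSS lay 25.2% ± 0.741 of peaks (SD, n = 2), 3.87-fold the 6.52% of shifted peaks. Exons away from a TSS held 3.72% ± 0.274 (3.22% of shifted peaks), introns 36.3% ± 0.613 (38.9%) and intergenic sequence 34.7% ± 0.401 (51.4%, 0.675-fold, SD, n = 2). All 100 shifts gave TSS shares from 6.20% to 6.89%. The shifts used the peaks of replicate 2 alone and could place them in assembly gaps, where no peak can be called. Such peaks count as intergenic, so the enrichment at TSSs and the intergenic depletion may be overstated. In replicate 1, 80.7% of TSS peaks overlapped a peak of replicate 2, against 72.0% of intronic peaks, and in replicate 2 the shares were 69.9% and 67.1%.

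The X chromosome had the lowest density of open sites apart from the Y chromosome. It carried 20.4 shared peaks per Mb, against 50.2 on chromosome 14 to 82.5 on chromosome 11 among autosomes, 0.336 of the autosomal median of 60.9. In single replicates the ratio was 0.341 and 0.378, a mean of 0.359 ± 0.0261 (SD, n = 2). Per protein-coding gene the X held 3.69 shared peaks, below all 19 autosomes, which ran from 4.39 on chromosome 7 to 10.4 on chromosome 12. The Y chromosome held 27 shared peaks. With 1 X chromosome no test applied.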

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

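Peaks outside the chromosomes compared in the report were looked at because a signal in parts of the data left unused would otherwise go unseen, and no test of a cause was run on them. Replicate 1 held 28 peaks on mitochondrial DNA with a median strength of 149.5 and replicate 2 held 23 with a median of 150, the top of the scale. With mitochondrial DNA included, 9 of the 10 strongest shared peaks lay on it. Unplaced and unlocalised scaffolds held 146 peaks in replicate 1, with a median strength of 37, and 165 in replicate 2, with a median of 47, against nuclear medians of 41 and 50.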

How the results depend on the processing

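The 5'-most TSS for distal counts and the results without replicate 1 or 2 for chromosomes, hotspots, motifs near lists and CpG-matched lists were chosen after seeing the data, and the other alternatives were planned and all run. The mean overlap of peaks was 65.2% with a reciprocal overlap of 50% and 80.6% for the stronger 50% of peaks, and that of hotspots of 200 bp or more was 80.8%. Spearman's rho was 0.908 with a reciprocal overlap of 50% and 0.881 for peaks over 1 kb from any TSS. The share of peaks at TSSs was 18.5% with a window of 500 bp, 34.7% with 2500 bp, 34.5% for the stronger 50% of peaks and 20.9% for hotspots, and that of intergenic peaks was 36.3%, 32.04%, 29.7% and 36.9% in the same order. The X to autosome ratio was 0.488 per protein-coding gene and 0.257 for the stronger 50% of peaks. Without replicate 1 or 2 the ranges were 24.7% to 25.8% for TSS peaks, 34.4% to 34.98% for intergenic peaks, 0.341 to 0.378 for the X ratio, 69.9% to 78.9% for hotspots, and 5 to 12 for the lists with more distal peaks, against 11 with shared peaks. The number of these lists was 6 at a distance of 100 kb, 9 at 20 kb, 11 with the 5'-most TSS, 7 for the stronger 50% of peaks and 6 with the nearest TSS only. With matching on the promoter CpG ratio 2 lists were higher at TSSs. Early neuron, one of the 6 called before, was still higher, heart gained a call, and the matched range of the other 5 reached 100%, so that no share could be called higher there. The Hox share of 71.8% then lay below its background and not above it, but was 84.6% with replicate 1 alone and not called. Germ cell genes were called lower in 3 settings without CpG matching, and yolk sac genes with 1 TSS per gene. With CpG matching germ cell genes were lower with both replicates, without replicate 1 (adjusted permutation p = 0.0014) and without replicate 2 (0.0021). With windows matched on GC content decile 1 motif instead of 3 was lower, since the homeobox (odds ratio 2.02) and FOX (1.24) motifs turned higher; homeobox was also higher (1.13) in windows with under 10% soft-masked repeat. By its construction the matching raised the GC content of the windows from 44.0% to 49.2%, against 49.9% in all peaks, and for the other changes the cause was not tested. Over single lists, motifs and pairs, 473 of 549 alternative values kept their side of the threshold, 52 of them with a change of sign that was called in neither setting. Another 55 lost a call, 16 gained one and 5 turned. Overlap and correlation could not be computed without a replicate. Read depth is unknown, and the higher median strength in replicate 2 (50 against 41) could not be set against it. No paired analysis was possible because the samples form a single group.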

Other observations

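The tests of gene families, of promoter peaks found in a single replicate, of X genes and X signal, and of the TSS window and position of Hox genes were chosen only after the result was seen, as were the set of 229 genes, the strength limit of 61 and the limit of 10 kb. Among gene families grouped by symbol, with 12 or more genes each, 41 of 196 had fewer open promoters than other genes and 79 had more. The families below are examples picked after seeing the values. No gene was open among 22 Defa defensins, 13 Ifna interferons, 25 Prl prolactins and 15 Taar trace amine receptors. Of the Mup urinary proteins 1 of 22 was open, of the Scgb secretoglobins 1 of 34, of the Krtap hair keratin-associated proteins 4 of 57 and of the Klk kallikreins 2 of 26. A lack of peaks in families of similar genes need not mean closed chromatin, since unique placement of reads there was not examined. Krt keratins were open in 12 of 53 cases and Cyp cytochromes P450 in 29 of 100 (adjusted p = 1.64e-15, Fisher's exact test). Zfp zinc finger genes were open in 346 of 394 cases (adjusted p = 7.59e-16, Fisher's exact test), all 26 Cdk and all 14 Psmd genes were open, and Rab GTPases were open in 65 of 69 cases, Eif initiation factors in 53 of 55, Rps ribosomal proteins in 42 of 44 and Hist histones in 57 of 67.

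Some promoter peaks were present in one replicate alone. Of 13324 genes with a replicate 1 promoter peak of strength 61 or more, 6 had no promoter peak in replicate 2. Of these, 5 were Hox genes, Hoxd8 (83), Hoxd9 (72), Hoxc8 (71), Hoxd11 (65) and Hoxa11 (61), and the other was Gm28230 (64), which lies in the HoxD cluster (chromosome 2, 74726728 to 74747918). The limit of 61 was taken from the weakest of these Hox genes, so their share among the 6 is not a test. In the other direction 34 of 14222 genes had none in replicate 1, with no Hox gene among them. They were led by Mpig6b (88), Tcf21 (88), Barx1 (76), Nkx2-1 (76), Nkx2-9 (75), Slc18b1 (75), Evx1 (74) and Htra4 (74).

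Around the 229 genes of the lists called higher for distal peaks, replicate 2 had more distal peaks than replicate 1, a mean of 25.5 per gene against 15.7. No biological explanation was tested, since the replicates form 1 group. The longer peak list of replicate 2, promoter CpG content and wide hotspots are each argued against as the whole cause. The median log2 ratio was 0.29 with equal numbers of peaks (0 to 0 in random lists, where the mean of 0.56 lay above -0.11 to 0.02), 0.36 against CpG-matched lists (0 to 0.18) and 0.36 without peaks in hotspots over 2 kb (0 to 0.15). The 229 genes came from lists with high counts in these same data, and the random lists were not matched on the number of distal peaks. In replicate 1 the mean over all genes was 8.29, and 7.88 without peaks in hotspots over 2 kb. Part of the excess did lie in wide hotspots, since without them the means were 17.8 and 11.7, and differences in read depth or between the embryos may contribute and stay open.

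On the X chromosome, the low density of peaks was set against 3 explanations. A lower number of genes is argued against as the whole cause by 3.69 shared peaks per gene, below the 4.39 of the lowest autosome. More repeat sequence is argued against as the whole cause by 40.1 shared peaks per Mb outside soft-masked repeat, below 79.3. Gene number and repeat sequence were not tested together. Signal was lower at open X promoters, with a median strength of 93 in replicate 1 over 498 genes, against 102 to 108 in autosomal genes of like promoter CpG content, and of 101 against 112 to 117 in replicate 2. Of all 948 X genes 52.5% were open, against 61.9% to 66.6% in matched autosomal lists. A lower signal per X locus, which in embryos of pooled sexes could come from the single X of males and X inactivation in females, is therefore a candidate explanation, and no biological explanation was tested. Peak strength and peak density come from the same peak calls, so the lower strength is not independent evidence.

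For the 11 Hox genes without a promoter peak in both replicates, peaks placed over 1 kb and up to 2.5 kb from the TSS were examined. They are argued against in 9, which had none within 2.5 kb in both replicates either, and stay open in the other 2, which had one. Peaks placed beyond 2.5 kb were not examined. Higher local background beside wide hotspots of replicate 2 was looked at but not decided. Of 6962 genes near them 0.575% lost their replicate 1 promoter peak, inside the 0.560% to 0.948% of genes of like strength, against 5 of 33 Hox genes. This is no like comparison for promoters beside a wide hotspot. In replicate 2, 3879 genes had a TSS inside one, against 4 of 39 Hox genes, and every hotspot overlapped a peak. With 10 kb or more of wide hotspot within 50 kb, 0 of 161 other genes lost their replicate 1 promoter peak, against 4 of 19 Hox genes, with the same limit. Position in the cluster may matter. Paralog groups 9 to 13 were open in 8 of 16 cases and groups 1 to 8 in 20 of 23 (Fisher's exact p = 0.0272). With replicate 1 alone these were 11 of 16 and 22 of 23. Over 8 boundaries tried, Fisher's exact p ran from 0.00125 to 0.323, with 6 under 0.05. The test treats clustered genes as independent. Position was not separated from cluster, since most genes of groups 9 to 13 lie in Hoxc and Hoxd. Those clusters were open in 5 of 9 and 4 of 9 cases, against 9 of 11 Hoxa and 10 of 10 Hoxb genes. No biological explanation was tested, and a higher local background, general or specific to these clusters, stays open.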
